A study of Homo sapiens with 9 samples.

How the data were processed

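RNA sequencing was measured in regulatory T cells (Tregs, the FOXP3-expressing T cells that restrain immune responses) taken from peripheral blood mononuclear cells of human donors and expanded in culture, per the labels' protocols, with rapamycin at 100 ng/mL and IL-2 at 500 IU. The cells were transfected with a small interfering RNA (siRNA) against RGS1, called siRGS1, or with a non-targeting scrambled siRNA, called siNT. The labels gave 9 libraries, 5 siNT and 4 siRGS1. The replicate number is the donor's number in the labels, so 4 donors have both libraries (pairs 1, 2, 3 and 5). The 9 libraries hold no siRGS1 library of the remaining donor, and siNT replicate 4 therefore has no partner.

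Libraries were made with a stranded mRNA kit, per the labels' protocols. bcl2fastq was named in the submitters' processing notes with no version. The aligner, the quantifier, the genome build and the annotation are not given in the sources used here, so no coordinates are printed and genes are given by symbol and Ensembl identifier. The authors deposited one table of 15356 genes on a log2 scale. The base and the offset of the deposited log2 values were read from the values: all 32 entries below 1e-12, or 100% of them, were whole multiples of the step that a base of 2 and an offset of 1 give, within 0.02 of a step, against 3.12% for a natural logarithm. The linear values had the same 75th percentile in each library, between 19.70 and 19.71, which is the trace of upper quartile scaling. The linear unit is not stated. Its sums lay between 564830 and 735550, read counts could not be recovered, and the depth of each library is unknown. No counting interval or detection limit can be given, and a difference is judged by the spread between libraries alone. A log2(value + 1) scale understates the changes of low genes.

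The test had been planned before the data were examined for read counts. The deposited log2 values need another test, so limma 3.58.1 in R 4.3.3 was used with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. Symbols were matched for 15327 of the 15356 identifiers. Y-linked genes and XIST were left out. Genes entered the test if their log2 value was at least 1 in at least 4 libraries, a filter set once the log2 scale was known, which left 10444. The comparison planned as the main one used all 9 libraries without a donor term. The second used the 8 paired libraries with the replicate number as a block. The pairing comes from the donor labels. As a check, the deviations of same-numbered libraries from their group means correlated above 0.1 in 4 of 4 pairs. No 2 libraries held identical values.

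RGS1 was also tested with an exact permutation test over the 126 splits of 9 libraries and an exact sign-flip test over the 16 sign patterns of 4 pairs. 24 gene lists and 7 lists of markers of other cell types were fixed before the data were examined. Lists with at least 3 tested members, 28 of them, were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists. The same lists were tested with an estimated correlation and with fry, which asks whether a list's genes move on balance one way. The other alternatives for the lists, among them each library or pair left out, kept the preset correlation. Genes were named by a rule fixed before the data were examined. RGS1 is always named. Up to 10 genes per direction are named if they pass 0.05 with one direction in all 4 pairs, and where fewer than 5 pass, the 5 smallest within-pair p-values are named and said to have missed the threshold. Up to 4 members of each list are named by within-pair p. Genes of the HLA, KIR, T cell receptor and immunoglobulin families, genes whose expression depends on common inherited deletions, pseudogenes, unnamed genes and genes with a mean linear value below 1 are not named. Some genes that the rule names are not reported here.

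The procedure was tested on 20 simulated data sets of 10444 genes with 200 changed genes. With 4 pairs and the block, 75.6% of changes of 0.3 on the log2 scale, 99.6% of changes of 0.6 and 100% of changes of 1 were called, and 7.75% of the calls were unchanged genes, above the nominal share. With all 9 libraries and no block, the shares were 1.49%, 37.6% and 70.9%. The simulated noise was independent between genes, unlike that of real libraries. The 200 changed genes also eased the adjusted threshold, so the shares do not carry over to data with few changed genes. In the real pairs RGS1 differed by -0.79 and still missed 0.05. For lists of 40 genes, camera within pairs gave a p under 0.05 for 0.375% of unchanged lists and 100% of lists raised by 0.1.

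Alternatives fixed before the data were examined were the donor block, another scaling (median-of-ratios on linear values), no filter on low values, each library or pair left out, the donor as a random effect (duplicateCorrelation, statmod 1.5.0), a threshold of 0.1, and a test against a fold change of 1.2. A pseudocount of 0.1, scaling to the total, quantile normalization, no mean-variance trend, covariates for the mitochondrial level and the length trend of each library, fry on the lists within pairs, and the RGS family list without RGS1 were added after the data had been seen. Sequence words and figures were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Transcript lengths and 3' untranslated regions (UTRs) came from GENCODE release 29 and may differ from the annotation behind the values.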

Results

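The comparison asked what lowering RGS1, a GTPase-activating protein that shortens signalling by G protein coupled receptors, does to the transcriptome of cultured human Tregs. The data were 5 siNT and 4 siRGS1 libraries, with 4 donors represented in both groups. The cells carried Treg transcripts in both groups. FOXP3, the lineage-defining transcription factor, stood at 7.66 ± 0.43 on the log2(value + 1) scale in siNT (SD, n = 5) and 7.70 ± 0.43 in siRGS1 (SD, n = 4). IL2RA, the high-affinity IL-2 receptor chain, stood at 7.92 ± 0.27 in siNT and 7.91 ± 0.20 in siRGS1. CD8A stood at 1.86 ± 1.10 in siNT and 2.12 ± 1.25 in siRGS1, and CD14, a monocyte marker, at 0.06 ± 0.08 and 0.07 ± 0.03. LYZ, from the list of monocyte and dendritic cell markers, was higher, at 3.95 ± 0.68 and 3.98 ± 0.84. The low CD14 therefore does not show that transcripts on that list were absent.

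RGS1 (ENSG00000090104) was lower in siRGS1 than in siNT in all 4 donor pairs. In linear values the siRGS1 library held 57.6% ± 10.5 of the RGS1 level of its siNT partner (SD, n = 4 pairs), between 46.9% and 66.7%. The within-pair difference was -0.79 ± 0.25 on the log2 scale (SD, n = 4 pairs), and RGS1 had the smallest within-pair p of all genes, with a limma adjusted p of 0.0883 that missed the threshold of 0.05. The exact two-sided sign-flip p was 0.125, the smallest that 4 pairs can give. Within pairs RGS1 passed in limma without pair 1 (adjusted p = 0.0254), and with a covariate for the mitochondrial level (adjusted p = 0.0303) or the length trend (adjusted p = 0.0163). It missed 0.05 in the other fits with the block, with an adjusted p of 0.193 without pair 2, 0.238 without pair 5, 0.699 without the filter on low values and 0.873 with scaling to the total, and it was lower in each of them. Donors differed in RGS1 by more than the knockdown did. The group levels were 6.31 ± 0.97 in siNT (SD, n = 5) and 5.55 ± 1.35 in siRGS1 (SD, n = 4), and the unpaired exact two-sided permutation p was 0.349.

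**Figure D1:**
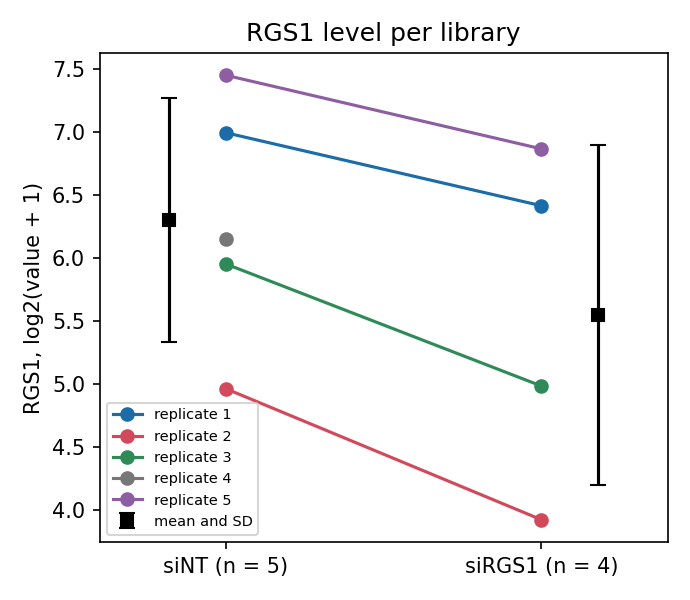
RGS1 level per library, in log2(value + 1), for 5 siNT and 4 siRGS1 libraries; points are libraries, lines join the 2 libraries of a donor, and squares with bars are group means and SDs. The line slopes down in all 4 pairs, while siRGS1 replicate 5, at 6.87, lies above siNT replicate 2, at 4.97.

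Across all 9 libraries no gene of 10444 passed an adjusted p of 0.05 in limma, and 19 had an unadjusted p under 0.05. Chance alone would give 522.2 on average. This fit leaves the differences between donors in its spread, where the donor correlation was 0.875. It is therefore conservative, and the low count of 19 does not speak against an effect. Within donor pairs no gene passed either, and 404 had an unadjusted p under 0.05, of which 182 were higher and 222 lower in siRGS1. With the donor as a random effect in limma, 0 genes passed and 422 had an unadjusted p under 0.05. The smallest adjusted p in that fit was 0.0537, and RGS1, at 0.367, did not have it. At an adjusted p of 0.1 within pairs 4 genes passed, RGS1, LIG1, MED17 and EIF3CL. Genes that kept one direction in all 4 pairs made up 11.7% of those tested, against 12.5% by chance.

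The genes that follow missed the threshold and are named for their small within-pair p. LIG1 (ENSG00000105486), the DNA ligase that joins Okazaki fragments, differed by -0.67 ± 0.22 (SD, n = 4 pairs), with a limma adjusted p of 0.0888. MED17 (ENSG00000042429), a subunit of the Mediator complex that links transcription factors to RNA polymerase II, differed by -0.43 ± 0.07 with the same adjusted p of 0.0888. GPR155 (ENSG00000163328), a lysosomal cholesterol sensor, differed by -0.26 ± 0.04, and ARHGAP25 (ENSG00000163219), a GTPase-activating protein for Rac, by -0.31 ± 0.11, each with an adjusted p of 0.231. All of these were lower in 4 of 4 pairs. Among the genes higher in 4 of 4 pairs, C1orf50 (ENSG00000164008) differed by 0.33 ± 0.13 with an adjusted p of 0.682. EIF3CL (ENSG00000205609) differed by 0.66 ± 0.18 with an adjusted p of 0.0888, ZNG1F (ENSG00000215126) by 0.84 ± 0.52 with 0.587, and PEDS1-UBE2V1 (ENSG00000124208) by 0.50 ± 0.33 with 0.929. The values of these last genes are uncertain, because EIF3CL and ZNG1F have near-identical copies and PEDS1-UBE2V1 is a readthrough gene. All 4 of the higher genes given here, C1orf50 included, had mean linear values below 5. With the mitochondrial covariate LIG1 and EIF3CL passed, with adjusted p of 0.0316 and 0.0303, and with scaling to the total both stood at 0.873.

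**Figure D2:**
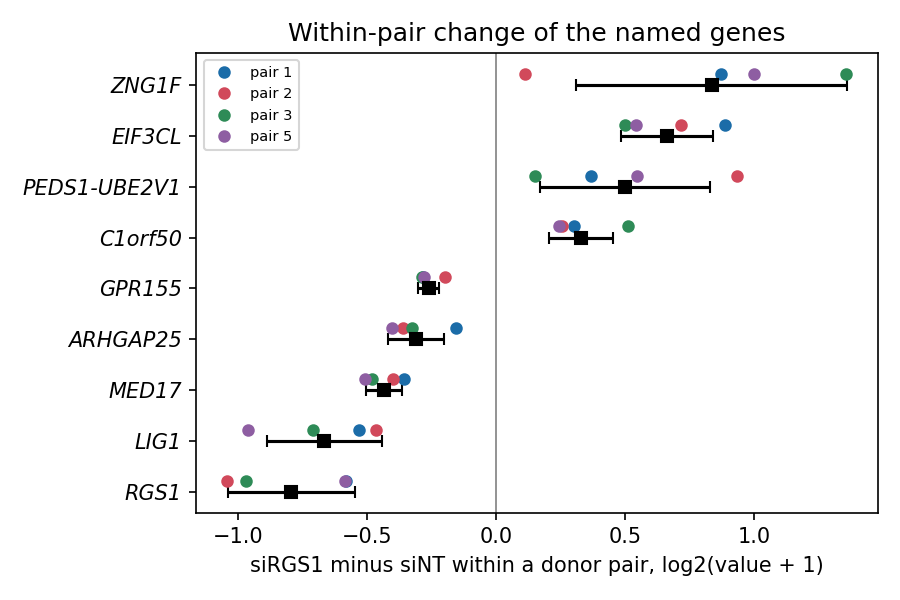
Within-pair change of 9 named genes, siRGS1 minus siNT in log2(value + 1); circles are the 4 donor pairs and squares with bars are means and SDs. RGS1 lies lowest, at -0.79, and no gene shown passed an adjusted p of 0.05 in this fit without covariates.

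Autophagy and metabolic genes were the groups of first interest, since the study's title names these programs. Of 46 core autophagy genes, 26 were higher and 20 lower within pairs (adjusted p = 0.884), and RB1CC1, which starts autophagosome formation, differed by -0.12 ± 0.13. Of 22 autophagy receptors and mitophagy genes, 17 were higher and 5 lower (adjusted p = 0.492), with PINK1, a mitophagy kinase, at -0.12 ± 0.08. Glycolysis had 17 higher and 8 lower of 25 (adjusted p = 0.246), with PFKM at 0.19 ± 0.05 and PFKFB3 at -0.17 ± 0.03. The nuclear oxidative phosphorylation genes had 44 higher and 35 lower of 79 (adjusted p = 0.884), the TCA cycle 15 and 9 of 24 (adjusted p = 0.637), and fatty acid oxidation 13 and 12 of 25 (adjusted p = 0.971). The oxidative phosphorylation list passed in opposite directions when 1 pair was left out, higher without pair 1 (adjusted p = 0.00316) and lower without pair 3 (adjusted p = 1.51e-05), and glycolysis passed as higher without pair 5 (adjusted p = 0.0466). At the preset correlation of 0.01 these p-values overstate the evidence. The correlation estimated with all 4 pairs was 0.631 for oxidative phosphorylation and 0.321 for glycolysis. Over all 9 libraries, oxidative phosphorylation passed as lower without siNT replicate 3 (adjusted p = 2.08e-07) and without siRGS1 replicate 5 (0.0498), the TCA cycle as lower without siNT replicate 3 (0.0099), and glycolysis as higher without siNT replicate 5 (0.0395). Leaving out a library of a paired donor leaves that donor in 1 group only, and this fit has no donor term. Differences between donors therefore cannot be told apart from the siRNA in such calls. Over these 6 lists no member passed over all genes or when adjusted over the list alone.

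6 of 28 lists passed camera within pairs at the preset correlation, and 0 passed with an estimated correlation or with fry. The mTORC1 and PI3K-AKT list had 33 of 42 members higher (adjusted p = 0.000769; adjusted p = 0.436 with an estimated correlation), and its median was 0.05 in each of the 4 pairs. Among its members were RRAGD at 0.19 ± 0.08, PIK3R1 at 0.12 ± 0.08 and RHEB, the activator of mTORC1, at 0.10 ± 0.05. Lysosomal genes had 50 of 65 higher (adjusted p = 0.00167; adjusted p = 0.91 with an estimated correlation), with CTSC at 0.16 ± 0.10 and MANBA at 0.15 ± 0.03, while the cathepsin CTSL stood at -0.21 ± 0.16. Without pair 3 the lysosomal call was lost (adjusted p = 0.408). In pair 3 the changes tilted toward short transcripts, with a Spearman rho of -0.30 between change and transcript length across genes. The lysosomal median there was 0.11, that of the mitochondrially encoded genes 0.37, and that of the monocyte and dendritic cell markers 0.20. With the length covariate and all 4 pairs the lysosomal call was kept (adjusted p = 0.000571), with a difference relative to other genes of 0.0306 against 0.0324 without the covariate. The rho was 0.175, 0.02, -0.30 and 0.167 in pairs 1, 2, 3 and 5. Tilts of both signs leave the covariate little room to move the mean difference. It therefore cannot settle the dependence on pair 3, without which the difference was 0.0084. Cholesterol biosynthesis had 20 of 25 higher (adjusted p = 0.00312; adjusted p = 0.74 with an estimated correlation), with the sterol synthesis enzymes CYP51A1 at 0.11 ± 0.12 and MSMO1 at 0.13 ± 0.18. Without pair 2 that call was lost (adjusted p = 0.14). Over all 9 libraries the cholesterol list passed as lower without siNT replicate 2 (adjusted p = 0.00366) or siRGS1 replicate 5 (0.0235), and as higher without siRGS1 replicate 2 (0.000316), siRGS1 replicate 3 (0.0381) or siNT replicate 5 (0.0446). Those fits have no donor term, and each left-out library unbalanced the donors between the groups. Cytosolic ribosomal proteins had 75 of 78 higher (adjusted p = 0.00167; adjusted p = 0.984 with an estimated correlation), but their medians were -0.11, 0.02, 0.28 and 0.04 in pairs 1, 2, 3 and 5, without pair 3 the direction turned, and with quantile normalization the call was lost (adjusted p = 0.651).

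Treg identity genes were lower in 23 and higher in 10 of 33 (adjusted p = 0.00409; adjusted p = 0.74 with an estimated correlation). The tumour necrosis factor receptors TNFRSF4 (OX40) and TNFRSF8 (CD30) differed by -0.17 ± 0.04 and -0.29 ± 0.25, and ENTPD1 (CD39), which degrades extracellular ATP, by -0.14 ± 0.07. IKZF2, which encodes the Treg factor Helios, went the other way at 0.14 ± 0.11. Without pair 2 the call was lost (adjusted p = 0.101). The RGS family list was lower in 8 of 9 (adjusted p = 0.00696; adjusted p = 0.74 with an estimated correlation), and it holds the targeted gene. Without RGS1 in the list the adjusted p was 0.243, without pair 2 it was 0.0516, and without the filter on low values 0.0654. RGS2 differed by -0.27 ± 0.24 and RGS12 by -0.15 ± 0.13.

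**Figure D3:**
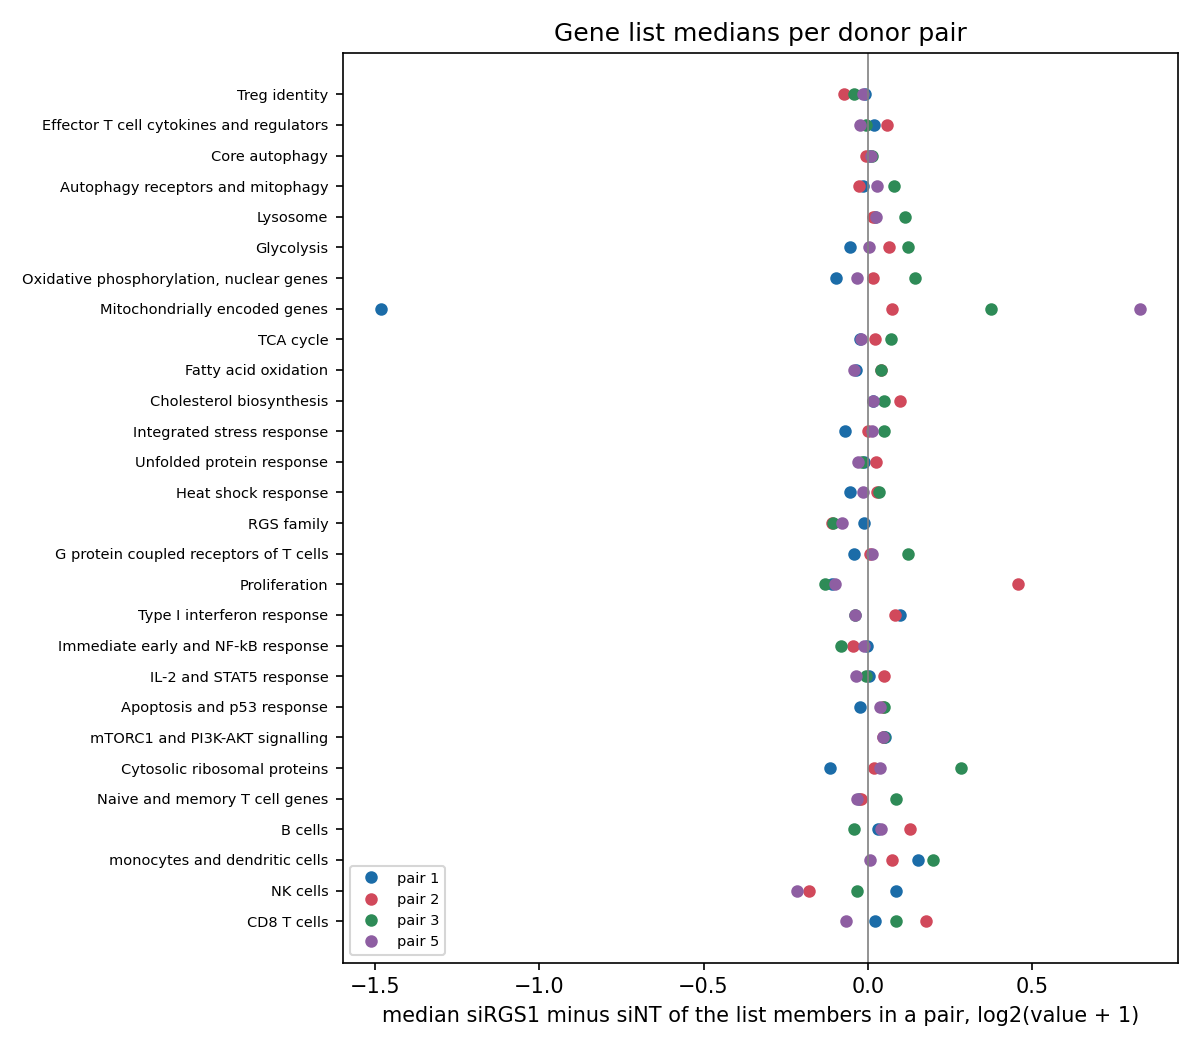
Median within-pair change of the tested members of each gene list, siRGS1 minus siNT in log2(value + 1), 1 point per donor pair. The mitochondrially encoded genes run from -1.48 to 0.83, and most other lists lie near 0.

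Over all 9 libraries without the donor term, 4 lists passed camera, all higher in siRGS1, and 0 passed with an estimated correlation or with fry. Lysosomal genes had 51 of 65 higher (adjusted p = 0.00256; adjusted p = 0.753 with an estimated correlation), and cytosolic ribosomal proteins 68 of 78 (adjusted p = 0.0197; adjusted p = 0.988 with an estimated correlation). Mitochondrially encoded genes had 13 of 13 higher (adjusted p = 0.00256; adjusted p = 0.988 with an estimated correlation), and the IL-2 and STAT5 response 22 of 27 (adjusted p = 0.00577; adjusted p = 0.753 with an estimated correlation). None of the 4 calls held without each library in turn. Without siNT replicate 4, which has no partner, the adjusted p was 0.832 for the mitochondrially encoded genes and 0.623 for the IL-2 and STAT5 response, and within pairs 0.927 and 0.637. The mitochondrial call was also lost without siRGS1 replicate 2 (adjusted p = 0.935), siRGS1 replicate 3 (0.0624) and siNT replicate 5 (0.276), and the IL-2 call without siRGS1 replicate 1 (0.103) and siRGS1 replicate 2 (0.232). The lysosomal call was lost without siRGS1 replicate 3 (adjusted p = 0.529) and siNT replicate 5 (0.232). The ribosomal call was lost without siNT replicate 1 (adjusted p = 0.341), siNT replicate 3 (0.383) and siNT replicate 5 (0.332), and it passed in the other direction without siRGS1 replicate 2 (4.04e-06). It was also lost without the filter on low values (adjusted p = 0.203) and with quantile normalization (0.566). Within pairs the mitochondrially encoded genes passed as higher without pair 1 (adjusted p = 1.56e-09) and as lower without pair 5 (0.00274). The correlation estimated within pairs was 0.88 for these genes and 0.952 for the ribosomal proteins. P-values at the preset of 0.01 overstate the evidence for such lists.

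The other lists did not pass within pairs with all 4 pairs. Members higher and lower were 7 and 10 of 17 effector cytokine genes (adjusted p = 0.884), 16 and 11 of 27 integrated stress response genes (adjusted p = 0.969), 11 and 11 of 22 unfolded protein response genes (adjusted p = 0.861), and 8 and 8 of 16 heat shock genes (adjusted p = 0.884). They were 20 and 16 of 36 chemoattractant and other receptors (adjusted p = 0.482), 17 and 17 of 34 type I interferon genes (adjusted p = 0.637), 13 and 20 of 33 immediate early and NF-kB genes (adjusted p = 0.187), 22 and 9 of 31 apoptosis and p53 genes (adjusted p = 0.14), and 14 and 8 of 22 naive and memory genes (adjusted p = 0.969). For fatty acid oxidation, the integrated stress response, the unfolded protein response and heat shock genes, the median, the mean and the test differed in sign within pairs. Proliferation genes had 29 and 15 of 44 (adjusted p = 0.637), with a median of 0.46 in pair 2 and between -0.13 and -0.10 in the others. That list passed as lower without pair 2 (adjusted p = 1.72e-17) and as higher without pair 3 (0.0127) or pair 5 (0.0214). These calls kept the preset correlation of 0.01, while the estimate for proliferation genes within pairs was 0.741. The preset counts genes that move together as nearly independent, so such p-values overstate the evidence. Apoptosis and p53 genes passed as higher without pair 1 (adjusted p = 0.0353), and type I interferon genes as higher without pair 3 (0.0265). Over all 9 libraries, the proliferation, type I interferon and integrated stress response lists each passed in both directions, depending on the library left out. In these fits and the ones that follow with a library left out, donor differences cannot be told apart from the siRNA. Effector cytokine genes, 13 of 17 higher in that fit, passed as higher without siNT replicate 5 (adjusted p = 0.000291), without siRGS1 replicate 3 (0.00642) and with scaling to the total (0.00394). Chemoattractant and other receptors passed as higher with scaling to the total (adjusted p = 0.0488) and without siNT replicate 5 (0.0446). Without siRGS1 replicate 3 the unfolded protein response (adjusted p = 0.0198) and the immediate early and NF-kB genes (0.00567) passed as higher, the latter also without siNT replicate 5 (0.0446). Adjusted over the list alone, 5 list members passed within pairs, RGS1, NCR3, GNLY and FGFBP2 among them, against 0 over all genes.

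Markers of other cell types did not pass with all libraries. Within pairs the adjusted p was 0.937 for B cells, 0.126 for monocytes and dendritic cells, 0.637 for NK cells and 0.492 for CD8 T cells. Without pair 5 the monocyte and dendritic cell list passed as higher (adjusted p = 0.0205), and over all 9 libraries the CD8 list passed as higher without siRGS1 replicate 1 (0.0069) or siNT replicate 5 (0.00761). The fits of the CD8 calls have no donor term, so donor differences may enter them. The mean linear level of the B cell markers was 7.42 ± 3.14 in siNT (SD, n = 5) and 6.15 ± 1.45 in siRGS1 (SD, n = 4), led by CD79B at 39.3. That of the monocyte and dendritic cell markers was 3.22 ± 0.99 in siNT and 3.38 ± 1.41 in siRGS1, led by LYZ at 16.1. Among the NK markers, the cytotoxic granule gene GNLY differed by -0.40 ± 0.40 and FGFBP2 by -0.20 ± 0.10, and the receptor NCR3 by 0.13 ± 0.03. The mean linear values of CD79B, of the B cell marker CD79A at 26.4 and of NCR3 at 23.4 lay above the 75th percentile of all genes in each library. Gamma delta T cell, platelet and erythroid markers had too few tested members for a test, and their mean linear levels in siRGS1 were 4.20, 0.0167 and 0.07.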

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

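Of 48 sets of values examined for 1 value far from the rest, 6 held one. Chance gives about 1 in 20, and lists that share a library are not independent. These sets were chosen after the data had been seen. The linear sum of siNT replicate 2 was 727970, and its gap to the next siNT library was 0.773 of the group's range. Among list medians within pairs, the proliferation genes of pair 2 stood at 0.46 (gap 0.947 of the range), the lysosomal genes of pair 3 at 0.11 (gap 0.921), the naive and memory genes of pair 3 at 0.09 (gap 0.894) and the apoptosis and p53 genes of pair 1 at -0.02 (gap 0.834). The change of GPR155 in pair 2 was -0.20, against -0.29 to -0.28 in the other pairs (gap 0.909).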

How the results depend on the processing

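Scaling to the total, quantile normalization, the pseudocount, the fit without a mean-variance trend, the covariates, fry on the lists within pairs, and the RGS family list without RGS1 were added after the data had been seen. With the replicate block on all 9 libraries the count of genes stayed at 0, and the RGS1 difference was -0.79 (adjusted p = 0.0867). The unpaired siNT replicate 4 is absorbed by its own block there. That fit therefore holds the same differences as the within-pair fit and is not a separate check of it. No alternative gave a called gene over all 9 libraries. Within pairs (replicate block), a threshold of 0.1 gave 4 genes, leaving out 1 pair gave 0 to 1 (RGS1 without pair 1), the mitochondrial covariate 3 (RGS1, LIG1 and EIF3CL) and the length covariate 1 (RGS1). RGS1 differed by -0.80 with the mitochondrial covariate (adjusted p = 0.0303) and by -0.79 with the length covariate (adjusted p = 0.0163). Leaving out each library gave -1.19 to -0.21, lowest without siRGS1 replicate 5 and nearest 0 without siRGS1 replicate 2, all lower. The 4 lists of all 9 libraries became 6 with scaling to the total, 6 with the replicate block, 3 without the low-value filter, 3 with quantile normalization, 0 with an estimated correlation and 0 with fry, 0 within pairs with an estimated correlation, and 3 to 9 when 1 library was left out (8 without siRGS1 replicate 1, siNT replicate 5 or siRGS1 replicate 5, 7 without siNT replicate 3, 9 without siRGS1 replicate 3). The 6 lists within pairs became 0 with an estimated correlation, 0 with fry, 3 with no replicate block, and 4 to 10 without 1 pair (10 without pair 5). Relative to other genes, the mitochondrially encoded list over all 9 libraries turned to -0.035 with the replicate block and without siNT replicate 4, which both give the mean over the pairs by construction. It ranged from -0.039 without siRGS1 replicate 2 to 0.669 without siRGS1 replicate 1. The ribosomal list ranged from -0.0964 without siRGS1 replicate 2 to 0.17 without siNT replicate 2, with -0.017 without siNT replicate 3, and was -0.0141 with quantile normalization; within pairs it ranged from -0.0262 without pair 3 to 0.114. Over the named genes and called lists, 240 of 293 values under alternatives kept their direction and side of the threshold, 41 lost the call, 5 gained it and 7 turned direction. The named genes had missed the threshold in the main fit and could not lose a call. The setting without a mean-variance trend left the list tests the same by construction. The 240 therefore overstate how stable the calls were. The cause of the lost and turned values was not tested. In the fit of all 9 libraries without a donor term, leaving out a library of a paired donor also unbalances the donors between the groups. The planned DESeq2 alternatives were not run, because the values are not counts. Depth is unknown, so its limits could not be set.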

Other observations

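The tests of sequence words and of mitochondrial transcripts were chosen after the results had been seen, and the splits of the libraries were set out before. The EIF3CL test was also recorded as set out before, but the gene was named by its within-pair p in these data. The mitochondrially encoded transcripts, which come from the mitochondrial genome, took 5.86% of linear values in siNT replicate 1 and 2.59% in siRGS1 replicate 1, but 2.63% in siNT replicate 5 and 4.32% in siRGS1 replicate 5.

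Splits of the libraries bear on the lists and on the structure of the samples. The real count of genes is 0, which any split reaches (100 of 100 splits drawn from 126, and 8 of 8 ways of swapping labels within pairs, where the highest other gave 1), so those comparisons decide nothing. The highest other split gave 3130 genes, which points to differences between donors. The donor correlation was 0.875, and 4 siRGS1 libraries lay closest to the siNT library of their own number. The 5 splits that kept both libraries of every paired donor together gave 1 to 3130 genes, while the 11 that parted all 4 pairs, the real one among them, gave 0. For lists, 90 of 100 splits gave at least the real 4, and the highest other gave 17. Among the 11 splits that parted all 4 pairs, 8 gave at least 4 and the most was 6, so chance cannot be excluded for the lists called without the donor term. The 8 swaps within pairs are too few for a share under 0.05; for lists the real count was 6, reached in 4 of 8, and the highest other was 12.

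Mitochondrially encoded transcripts moved in opposite directions between pairs. The median of the 13 was -1.48, 0.07, 0.37 and 0.83 in pairs 1, 2, 3 and 5. The Spearman rho of the changes with transcript length across genes was 0.175, 0.02, -0.30 and 0.167 in the same order, so it turned with the median between pairs 1 and 3 but not between pairs 1 and 5, which argues against a length trend as the whole cause and leaves a part in pairs 1 and 3 open. A lower RGS1 level as the whole cause is argued against by the same medians, since RGS1 was lower in all 4 pairs while the lowest median was -1.48 and the highest 0.83. RNA quality and handling of single libraries may contribute and were not tested.

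Words of 6 bases in 3' UTRs were compared with the within-pair changes, because an siRNA can lower transcripts that match its seed, and the siRNA sequences are not given in the sources used here. Of 53 genes with a 3' UTR, an unadjusted p under 0.01 and a lower level in siRGS1, 35 held AGAGAT, or 66.0%, against 39.2% in genes matched on UTR length, GC content and expression. The word was found by searching 4096, and in the same search 93.2% of 1000 matched sets gave a best word with less excess, short of the bound set for the test, so UTR length, composition and the search itself may account for it. With 1 pair left out, the most negative word was AGAGAT in 2 of 4 cases and CGGGGG in the others, where AGAGAT ranked 61 and 6, and the word found held at the set bound in the left-out pair in 2 of 4. A seed effect stays untested without the siRNA sequences: the z of AGAGAT, -5.60 to -1.49 over the pairs, follows largely from its choice on these pairs, the median change of all genes was 0.00263 with the word and 0.00474 without it, and 33.0% of all words of that length lie in the RGS1 mRNA, AGAGAT among them.

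EIF3CL, which passed 0.05 within pairs only with the mitochondrial covariate, may take its difference from reads shared with EIF3C. EIF3C stood at a mean linear value of 172.4 against 4.71 for EIF3CL, so a small shift of reads would be enough. EIF3C was higher in 1 of 4 pairs, with a mean change of -0.02 ± 0.07 (SD, n = 4 pairs), a spread too wide to settle it.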
